A study of Homo sapiens with 12 samples.

How the data were processed

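Total RNA of day-30 cardioids grown from WTC11 induced pluripotent stem cells was sequenced in 12 libraries, 3 for each of 4 genotypes. Per the labels' protocols, cardioids were pooled by genotype and differentiation round, ribosomal RNA was depleted, and directional libraries were read as paired ends. Per the submitters' processing notes, reads were trimmed and aligned with STAR to GRCh38 in the snakePipes RNA-seq module, and comparisons used a formula with batch and condition. The notes name annotation release 114 of Ensembl, but the gene identifier versions and clone-style names in the deposited tables belong to an older annotation. The counter, its strand setting and the DESeq2 version are not given in the sources used here, so counts of antisense and overlapping genes are uncertain.

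The authors deposited raw whole-number counts per gene and library, with 58780 genes and no normalization. For each altered line against wild type they also deposited a DESeq2 results table. In these deposited tables the log2 fold change and its standard error are on the log2 scale, the mean normalized count is a signal averaged over the libraries used, and the test statistic is a score, the fold change divided by its standard error. The p-value and the adjusted p-value in the deposited tables are those of DESeq2, per the file headers. The weights of the libraries behind the deposited signal were solved from the counts, which showed that only batches A and C entered the tables. This was then checked by running DESeq2 on those libraries.

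All 12 columns of counts were matched to samples by their titles, with 0 columns unmatched. Groups came from the genotype in the labels and blocks from the batch letter. Pairing was checked on log2 CPM after removal of genotype means. The 18 pairs of libraries from the same batch correlated at 0.18 to 0.64 (median 0.43), all 18 above 0.1, and 12 of 12 libraries correlated best with their own batch. Pairs with the same replicate number ran from -0.5 to 0.62 (median -0.2), with 7 of 18 above 0.1 and 1 of 12 libraries best with its own number. Batch was therefore kept as the block, and the replicate number was used only as an alternative. A genotype's libraries come from different rounds of one line. Gene p-values measure how genotype differences vary between rounds, not between independently derived lines.

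Genes were kept with filterByExpr in edgeR 4.0.16 (minimum count 10, by genotype), which left 21844. Libraries were scaled by TMM. A quasi-likelihood model with robust dispersion, genotype and batch was fitted to all 12 libraries with 6 residual degrees of freedom and a common dispersion of 0.122. Each contrast was tested with the quasi-likelihood F test, a two-sided test, and p-values were adjusted by Benjamini and Hochberg over the genes kept, with a threshold of 0.05. The standard error printed beside a fold change is its absolute value divided by the square root of F. CPM values are TMM-scaled, and log2 CPM uses a prior count of 2. For genes with 1 to 3 counts in a group the ratio of rates is given with an exact binomial 95% interval, which covers counting error only. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used besides edgeR.

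A set of 42 gene lists for heart muscle, mitochondria, metabolism, RNA granules, stress responses and cell types was written before the data were examined, as were the tests, thresholds, other settings to try and the rule for named genes. Of 982 list symbols 980 were found in the deposited table, through current symbols that matched 58252 of its 58780 identifiers. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 42 lists. Camera compares a list with the other genes. It was repeated with an estimated correlation, and fry tested whether a list moved, without comparing it with other genes. Beside each list stands how many members passed over all genes and adjusted over the list alone.

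Named genes are RBM20 in every library, and for each line against wild type up to 10 genes higher and 10 lower. These had the largest fold change among those past the threshold, a mean of at least 5 CPM in the higher group, the same direction in all 3 batches and a proper symbol. Between lines the limit was 5 in each direction. For each list called, up to 4 members with the smallest p were eligible, and TTN, RYR2, CAMK2D, LDB3, MYH6, MYH7, NPPA, NPPB, PPARGC1A and ATF4 were fixed. Genes outside this rule are marked in the text as chosen after their values were seen. Where few genes passed, those that are reported are all named; a few genes are not reported here. Coordinates are GRCh38 positions of a GENCODE annotation, matched by gene identifier.

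Resemblance between comparisons that share wild type was set against 10 simulated sets of unchanged groups. With 3 wild-type libraries the controls could not be divided between comparisons with 2 in each part. Every count was also recomputed over the other ways of splitting the 6 libraries of a pair of genotypes.

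The scripts were tested on 20947 uncorrelated simulated genes with the means and sizes of the RQ and wild-type libraries. Of 50 genes changed per size, edgeR recovered 2 at 1.5-fold, 16 at 2-fold, 46 at 4-fold and 49 at 8-fold. It made 119 calls, 6 of unchanged genes, and 0 in a comparison without change. DESeq2 made 182 calls, 50 of unchanged genes. A 1.5-fold rise of one list gave a camera adjusted p of 3.17e-19 (0.00338 with an estimated correlation), with 0 of 37 other lists called. The preset correlation was thus not tested.

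The other settings set beforehand were DESeq2 in place of edgeR, its size factors (RLE) in edgeR, no filter on low counts, no batch term, the replicate number as block, only the libraries compared, leaving out genes of mitochondrial DNA and ribosomal RNA, and leaving out each library in turn. For lists the estimated correlation and fry were added. A fit with batches A and C only, and a covariate for cell content, were chosen after seeing the data. Exon use and RNA stability, named in the processing notes, need data other than gene counts and were left out.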

Results

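Gene-level RNA counts were measured in day-30 cardioids, heart-like organoids grown from the human induced pluripotent stem cell line WTC11. The 12 libraries covered 4 genotypes with 3 libraries each: wild type and lines labelled RBM20 KO, RBM20 PL and RBM20 RQ, called the KO, PL and RQ lines here. The labels do not spell out the alteration behind PL and RQ. Each genotype had 1 library in each of 3 batches, A, B and C. Count totals ran from 13873618 to 23370130 per library, and 21844 of 58780 genes had enough counts to be tested. RBM20 is a splicing regulator of heart muscle, and the series title concerns ribonucleoprotein granules and mitochondrial activity in the cardiomyopathy linked to it. The comparisons below ask which genes and gene groups differed in RNA level between each altered line and wild type, and between the altered lines; exon use is outside gene counts. Levels are in CPM, counts scaled to library size, as mean and SD over the 3 libraries of a genotype. Fold changes are on the log2 scale with their standard error (SE), from the edgeR fit of all 12 libraries with batch as a term, and 3 values in a row are the differences within batches A, B and C. A pair in parentheses after a left-out library is the median and adjusted p of the list without it.

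Batch marked the libraries strongly. Sarcomere genes, which build the contractile apparatus, had a mean of 8.99 log2 CPM in the 4 libraries of batch B (SD 0.13), against 7.2 in batch A (SD 0.53) and 7.3 in batch C (SD 0.42). TTN, the giant sarcomere protein titin, took 6.28 to 8.53% of the counts in batch B and 1.05 to 4.04% in the other batches. Fibroblast markers had a mean of 6.38 in batch B (SD 1.53), 7.8 in A and 8.01 in C. Endothelial markers stood at 3.76 in batch B, 5.42 in A and 6.3 in C, and foregut and hepatic markers at 1.67, 5.38 and 5.56. The wild-type library of batch B had the lowest share of the fibroblast collagen COL3A1, 0.16% of its counts, where the other 11 libraries had 0.58 to 5.02%.

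**Figure D1:**
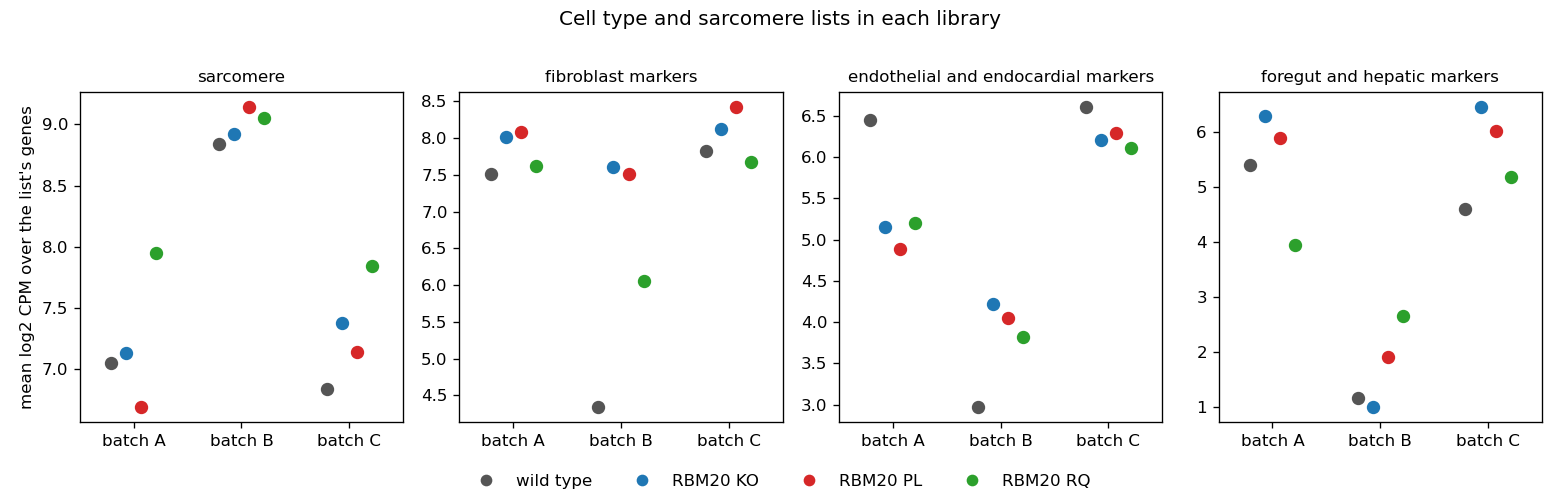
Mean log2 CPM of gene lists per library, with a point for each library, the batch on the horizontal axis and the genotype as colour. Sarcomere genes averaged 8.99 in batch B and 7.2 and 7.3 in batches A and C, while foregut and hepatic markers averaged 1.67 in batch B and 5.38 and 5.56 in the others.

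RBM20 RNA (ENSG00000203867.7, GRCh38 chromosome 10, 110644336 to 110839468, plus strand, protein coding) was counted in every library. In wild type it was 78.5, 90.0 and 331 CPM in replicates 1, 2 and 3, of batches C, A and B. The KO line had 57.2, 79.9 and 253 CPM in batches A, C and B. The PL line had 82.7, 398 and 109 CPM in batches A, B and C, and the RQ line 356, 176 and 215 CPM in batches B, C and A. Genotype means were 166 (SD 142) in wild type, 130 (SD 107) in KO, 197 (SD 175) in PL and 249 (SD 94.9) in RQ. Against wild type the fold change was -0.34 for KO, 0.21 (SE 0.25) for PL and 0.89 (SE 0.25) for RQ, the last with 1.25, 0.11 and 1.16 by batch. Adjusted p was 0.869, 0.963 and 0.746, so no difference in RBM20 RNA passed the threshold. With no filter on low counts the RQ value was 0.9 at an adjusted p of 0.00404.

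**Figure D2:**
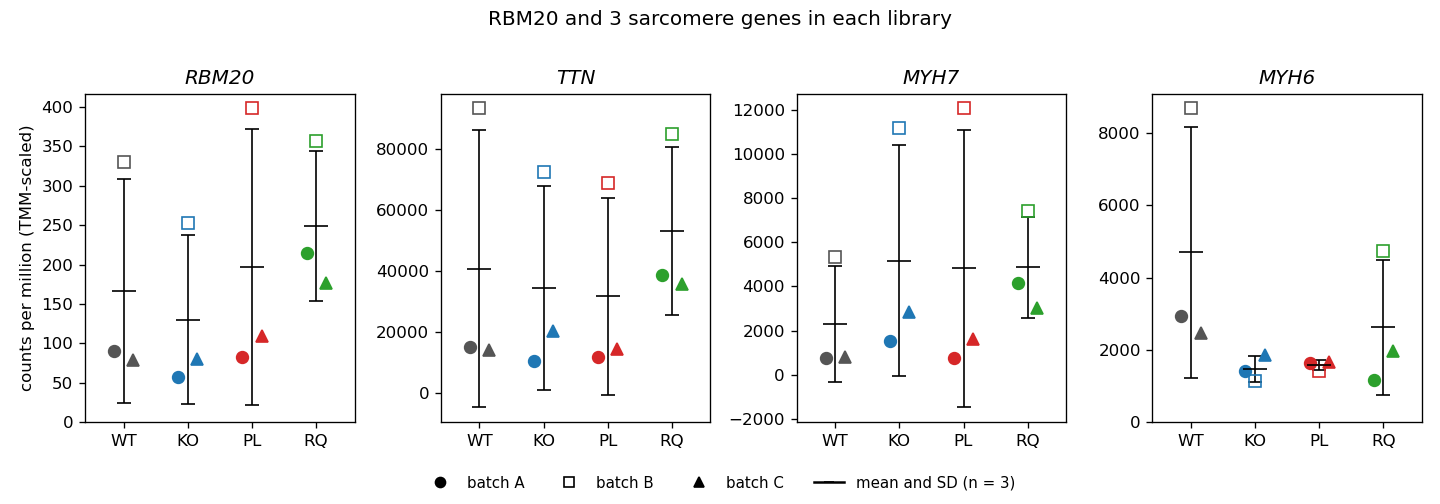
RBM20, TTN, MYH7 and MYH6 in each library (CPM, TMM-scaled), by genotype, with the mean and SD (n = 3) and the batch as marker. RBM20 spans 57.2 to 398 CPM, and the batch B library is the highest of each genotype for RBM20.

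In the KO line, the 13 mRNAs encoded by mitochondrial DNA, which make core subunits of the respiratory chain and ATP synthase, were lower than in wild type. Their median fold change was -0.71, none of the 13 lay above 0, and the within-batch means were close, -0.84, -0.7 and -0.71 (mean -0.75, SD 0.08). MT-ND5 had 253 CPM (SD 56.0) in KO and 456 (SD 44.1) in wild type, MT-ND1 had 100.1 (SD 8.18) and 190 (SD 31.5), and MT-ND2 had 77.4 (SD 6.66) and 146 (SD 33.7). All genes of mitochondrial DNA took 0.261, 0.37 and 0.368% of counts in KO and 0.49, 0.492 and 0.542% in wild type. Camera gave the mRNAs an adjusted p of 1.37e-09, and an adjusted p = 0.88 with an estimated correlation. No single member passed over all genes tested or adjusted over the list alone. Nuclear genes of the same machinery had medians near 0. Complex I had 0.09 (adjusted p 0.72), complexes II and III 0.04 (0.953, mean -0.01, camera downward) and complex IV -0.06 (0.214). The complex IV mean, COX7A1 included, was lower in KO in each batch. ATP synthase had -0.13 (0.424) and the mitochondrial ribosome 0.01 (0.72). Genes of mitochondrial biogenesis, import and dynamics had -0.03 (0.804), sarcomere genes 0.03 (0.0613), and stress granule and P-body genes -0.11 (0.0613).

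Extracellular matrix and fibroblast genes were higher in the KO line. All 14 fibroblast markers lay above 0, with a median of 1.17, and 33 of 38 extracellular matrix genes did, with a median of 0.78. COL3A1 averaged 30250 CPM (SD 12330) in KO and 14260 (SD 10970) in wild type, with differences of 1.12, 3.23 and 0.59. The 2 lists had camera adjusted p values of 2.88e-11 and 1.22e-10, and an adjusted p = 0.88 and 0.946 with an estimated correlation. Their within-batch means were 0.5, 3.26 and 0.29 for fibroblast markers and 0.15, 2.18 and 0.05 for matrix genes, so that most of the difference came from batch B, where the wild-type library had the least collagen. The fibroblast median was 0.73 without KO replicate 3 and 0.54 without wild-type replicate 3, and the matrix median 0.37 and 0.27 (1.19 without wild-type replicate 2). With batches A and C only the matrix median was 0.12 and its call ended (adjusted p 0.0944). No member of either list passed over all genes tested or adjusted over the list alone.

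Genes of the secretory and sterol pathways were also higher in KO. Endoplasmic reticulum stress genes had a median of 0.22 with 16 of 17 above 0, and 6 of them rose when adjusted over the list alone, though none did over all genes. XBP1, a transcription factor of the unfolded protein response, had a fold change of 1 (SE 0.27), and the chaperones HSPA5 and CALR had 0.58 (SE 0.2) and 0.53 (SE 0.18). The list gave a camera adjusted p of 1.98e-05, an adjusted p = 0.619 with an estimated correlation, and 0.41, 0.4 and 0.15 by batch. Cholesterol synthesis genes had a median of 0.45 with 23 of 24 above 0 (camera adjusted p 1.98e-09; adjusted p = 0.907 with an estimated correlation; 0.95, 0.06 and 0.39 by batch). The sterol enzymes CYP51A1 and DHCR7 had 1.05 (SE 0.4) and 0.56 (SE 0.23). Foregut and hepatic markers had a median of 0.95 with 16 of 19 above 0, at an adjusted p of 0.000632 and an adjusted p = 0.946 with an estimated correlation. Their batch means were 0.89, -0.17 and 1.86, and the serum protein genes TTR and ALB had fold changes of 2.72 (SE 0.95) and 2.11 (SE 1.03). No cholesterol, foregut or hepatic gene passed over all genes or adjusted over its list alone. Camera no longer called, with 1 library left out, foregut and hepatic markers without KO replicate 1 (0.8, 0.0875). The cholesterol median was 0.19 without KO replicate 1.

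Of the other lists, cytosolic ribosome genes had a median of 0.14 in KO (54 of 72 above 0; adjusted p 0.000632, adjusted p = 0.949 with an estimated correlation). Immediate early genes had 0.35 (16 of 21; adjusted p 0.0154, adjusted p = 0.949 with an estimated correlation; 0, 0.77 and -0.14 by batch). Hypoxia response genes had -0.36, with 3 of 20 above 0, at an adjusted p of 9.44e-05 and an adjusted p = 0.946 with an estimated correlation; adjusted over the list alone 2 fell. Their batch means were 0.2, -0.91 and -0.28. Glycolysis genes had -0.2, with 5 of 25 above 0 (adjusted p 0.0051, adjusted p = 0.949 with an estimated correlation; 0.03, -0.75 and 0.07 by batch), and PDK1, which restrains pyruvate oxidation, had -0.68 (SE 0.2). The contraction genes MYH7 and MYH6, the slow and fast cardiac myosins, had 1.31 (SE 0.45) and -1.43 (SE 0.49) at adjusted p values of 0.789 and 0.795. TTN had -0.11 (SE 0.33), RYR2, the calcium release channel, -0.38 (SE 0.26), PPARGC1A, a coactivator of mitochondrial genes, -0.6 (SE 0.22), and ATF4, of the integrated stress response, 0.28 (SE 0.22). RBM20 splicing targets had a median RNA fold change of -0.06 (adjusted p 0.804). Leaving out 1 library ended the camera call of cytosolic ribosome genes without wild-type replicate 3 (0.04, 0.345); immediate early genes without KO replicate 1 (0.25, 0.219), KO replicate 3 (0.19, 0.476), wild-type replicate 1 (0.32, 0.0666) or wild-type replicate 3 (0.19, 0.345); hypoxia response genes without KO replicate 3 (-0.11, 0.476) or wild-type replicate 3 (-0.21, 0.0517); glycolysis genes without KO replicate 3 (-0.03, 0.879) or wild-type replicate 3 (-0.05, 0.582).

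For single genes, edgeR called 0 between KO and wild type, with 1323 at an unadjusted p below 0.05 where 1092 of 21844 are expected by chance, and DESeq2 called 914. The smallest adjusted p was 0.112. The leading genes, chosen after their values were seen, were COX7A1 and ZNF208, both at 0.112. COX7A1, a muscle-type subunit of respiratory complex IV, had 0.24 CPM (SD 0.321) in KO and 5.05 (SD 3.33) in wild type, a fold change of -4.72 (SE 0.67). ZNF208, a zinc finger gene, had 9.65 CPM (SD 0.753) and 26.3 (SD 4.98), a fold change of -1.44 (SE 0.21) with -1.36, -1.6 and -1.31 by batch. Of the 42 lists, camera called 10, 7 higher and 3 lower, and 0 with an estimated correlation; 2 genes passed without wild-type replicate 3.

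In the PL line, GC and INPP5F were higher than in wild type. GC (ENSG00000145321.12, chromosome 4, 71741696 to 71804041, minus strand), which encodes the vitamin D binding protein of plasma, had 24.2 CPM (SD 18.0) in PL and 2.95 (SD 1.81) in wild type, a fold change of 3.03 (SE 0.38, adjusted p 0.0313) with 2.29, 3.37 and 3.22 by batch. INPP5F (ENSG00000198825.13, chromosome 10, 119726042 to 119829147, plus strand), an inositol phosphatase of endosomes, had 85.9 CPM (SD 21.5) and 26.4 (SD 3.73), a fold change of 1.69 (SE 0.22, adjusted p 0.0313) with 2.11, 1.03 and 1.88. They were the only 2 genes called by edgeR in this comparison, where 1247 had an unadjusted p below 0.05 and DESeq2 called 892. The count was 0 without PL replicate 3 or wild-type replicate 1 or 2, 1 without PL replicate 2, and 4 without PL replicate 1.

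The extracellular matrix program was higher in PL than in wild type, with 35 of 38 genes above 0 and a median of 1.14. Adjusted over the list alone 18 of them rose, though none passed over all genes. TIMP1, an inhibitor of matrix proteases, had 1.45 (SE 0.35), the collagen gene COL5A1 1.23 (SE 0.31), the matrix protease MMP14 1.44 (SE 0.39) and the crosslinking enzyme LOXL2 1.17 (SE 0.33). The list had a camera adjusted p of 8.61e-28, an adjusted p = 0.361 with an estimated correlation, and 0.33, 2.31 and 0.93 by batch. Fibroblast markers had a median of 1.27 with 13 of 14 above 0 (camera adjusted p 1.47e-12; adjusted p = 0.373 with an estimated correlation), and 0.57, 3.17 and 0.59 by batch. COL1A1 was 0.11, 3.89 and 1.99 by batch. TGF-beta response genes had a median of 0.34 (16 of 20; adjusted p 2.67e-05, adjusted p = 0.373 with an estimated correlation), with the smooth muscle gene TAGLN at 1.82 (SE 0.59) and the TGF-beta binding protein LTBP2 at 0.88 (SE 0.3); adjusted over the list alone 1 rose. Cardiac stress and natriuretic genes had 0.42 (14 of 18; adjusted p 0.00087, adjusted p = 0.458 with an estimated correlation; -0.07, 0.8 and 0.58 by batch), and 1 rose adjusted over the list alone. Their median was 0.12 with batches A and C only, 0.24 without wild-type replicate 3 and 0.64 without wild-type replicate 1. Without wild-type replicate 3 the matrix and fibroblast medians were 0.69 and 0.68, and the TGF-beta median was 0.55, 0.52 and 0.52 without PL replicate 1, wild-type replicate 1 and wild-type replicate 2. The natriuretic peptide genes NPPA and NPPB had 113 and 39.4 CPM in PL and 90.3 and 29.9 in wild type.

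Endoplasmic reticulum stress genes were higher in PL too, with a median of 0.3, 16 of 17 above 0, and 0.29, 0.5 and 0.31 by batch. Adjusted over the list alone 6 rose, and over all genes 0; the camera adjusted p was 1.05e-06, and an adjusted p = 0.34 resulted with an estimated correlation. CRELD2 and PDIA4, both of protein folding in that compartment, had 0.8 (SE 0.22) and 0.61 (SE 0.17). Foregut and hepatic markers had a median of 0.81 with 17 of 19 above 0 and 0.49, 0.75 and 1.43 by batch (adjusted p 0.000145, adjusted p = 0.458 with an estimated correlation). ALB had 2.73 (SE 1.06) and TTR 1.99 (SE 0.94). Cholesterol synthesis genes had 0.22 (20 of 24; adjusted p 0.00809, adjusted p = 0.745 with an estimated correlation), neural markers 0.43 (8 of 11; 0.00883, adjusted p = 0.361 with an estimated correlation) and immediate early genes 0.29 (15 of 21; 0.0466, adjusted p = 0.806 with an estimated correlation). The camera call ended for cholesterol synthesis genes without wild-type replicate 2 (0.13, 0.29); neural markers without PL replicate 1 (0.32, 0.0864), PL replicate 2 (0.3, 0.147), wild-type replicate 2 (0.57, 0.0555) or wild-type replicate 3 (0.36, 0.551); immediate early genes without PL replicate 2 (0.15, 0.115), PL replicate 3 (0.09, 0.506), wild-type replicate 1 (0.15, 0.122) or wild-type replicate 3 (0.01, 0.645). The endoplasmic reticulum stress median was 0.49 without wild-type replicate 1.

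Lower in PL were glycolysis genes, with a median of -0.29 and 1 of 25 above 0 (camera adjusted p 9.16e-06; adjusted p = 0.458 with an estimated correlation; -0.38, -0.42 and -0.08 by batch). SLC2A1, the basal glucose transporter, had -0.75 (SE 0.3) with -0.73, -0.77 and -0.73, and PDK1 -0.71 (SE 0.2). Hypoxia response genes, which share several members with glycolysis, had -0.3 with 2 of 20 above 0 (adjusted p 2.67e-05, adjusted p = 0.458 with an estimated correlation). The mitochondrial mRNAs had -0.45 with none of 13 above 0, an adjusted p of 1.86e-05, and an adjusted p = 0.458 with an estimated correlation; their batch means, 0.08, -0.24 and -1.44, were far apart. Stress granule and P-body genes had -0.12 with 6 of 40 above 0 (adjusted p 0.0109, adjusted p = 0.723 with an estimated correlation; 0.16, -0.19 and -0.31 by batch), and their members FXR1 and DCP1A, a granule protein and a decapping activator, had -0.35 (SE 0.19) and -0.28 (SE 0.16). Heat shock genes had -0.18 (5 of 21; adjusted p 0.00809, adjusted p = 0.458 with an estimated correlation), with HSP90AA1 at -0.63 (SE 0.2) and HSPA1A at -0.59. Endothelial markers had -0.42 (3 of 17; adjusted p 0.0359, adjusted p = 0.852 with an estimated correlation), and -1.56, 1.08 and -0.31 by batch. Calls that ended with 1 library left out were those of mitochondrial mRNAs without PL replicate 3 (-0.02, 0.543); stress granule and P-body genes without PL replicate 2 (-0.1, 0.108), PL replicate 3 (-0.06, 0.323), wild-type replicate 1 (-0.09, 0.255) or wild-type replicate 3 (-0.09, 0.0955); heat shock genes without PL replicate 1 (-0.23, 0.504) or PL replicate 3 (-0.14, 0.0699); endothelial markers without PL replicate 1 (-0.13, 0.801), wild-type replicate 1 (-0.46, 0.0854) or wild-type replicate 2 (0.24, 0.15). Without wild-type replicate 3 the glycolysis and hypoxia medians were -0.17 and -0.19; glycolysis was also at -0.19 without PL replicate 1, and hypoxia at -0.18 without PL replicate 3 and -0.47 without wild-type replicate 2.

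No contraction gene named here passed between PL and wild type. The sarcomere list had a median of -0.12, a mean of 0.09 and a camera direction downward (adjusted p 0.977), so these differ in sign. TTN had -0.27 (SE 0.33, adjusted p 0.97), MYH6 -1.35 (SE 0.49, 0.773), MYH7 0.83 (SE 0.45, 0.928) and PPARGC1A -0.66 (SE 0.22, 0.706). RBM20 splicing targets had a median of -0.14 (adjusted p 0.196) and complex I genes one of 0.03. Of 42 lists camera called 15, 9 higher and 6 lower, and 0 with an estimated correlation.

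In the RQ line, 4 genes passed the edgeR threshold against wild type, and 3 of them are described here. ZDBF2 (ENSG00000204186.8, chromosome 2, 206274663 to 206314427, plus strand), a paternally expressed imprinted gene, had 139 CPM (SD 13.4) in RQ and 5.68 (SD 3.74) in wild type, a fold change of 4.88 (SE 0.45, adjusted p 0.00798) with 3.63, 5.74 and 4.98 by batch. ITGA7 (ENSG00000135424.16, chromosome 12, 55684568 to 55716404, minus strand), the laminin receptor integrin of muscle, had 84.2 CPM (SD 62.2) and 24.7 (SD 23.2), a fold change of 1.94 (SE 0.25, adjusted p 0.0343) with 2.14, 1.6 and 2.01. KO (65.5 CPM) and PL (69.9) exceeded wild type too, in each batch. GC had 17.5 CPM (SD 7.74), a fold change of 2.76 (SE 0.38, adjusted p 0.0343). At an unadjusted p below 0.05 there were 853 genes, and DESeq2 called 744. The edgeR count was 37 without RQ replicate 1 and 0 to 9 without others.

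Contractile and calcium genes were higher in RQ than in wild type. Of 34 sarcomere genes 31 lay above 0, with a median of 0.64, and 8 rose adjusted over the list alone, 0 over all genes. The regulatory light chain MYL2 of ventricular muscle had 2.58 (SE 0.59) with 3.63, 0.63 and 2.72 by batch, MYH7 had 1.8 (SE 0.46) with 2.5, 0.48 and 1.91, and LMOD3, of thin filament assembly, had 2.74 (SE 0.69). TTN had 0.9 (SE 0.33) with 1.35, -0.14 and 1.35. The list had a camera adjusted p of 2.58e-21 and an adjusted p = 0.454 with an estimated correlation; its batch means were 0.9, 0.21 and 0.99 (mean 0.7, SD 0.43). Ventricular genes had a median of 0.72 with 10 of 10 above 0 and 3 risen adjusted over the list alone (camera adjusted p 1.55e-09; adjusted p = 0.454 with an estimated correlation; 1.18, 0.2 and 1.23 by batch). FHL2, a LIM protein of the sarcomere, had 1.03 (SE 0.24). Genes whose transcripts RBM20 splices had a median of 0.4 with 20 of 24 above 0 (camera adjusted p 1.55e-09; adjusted p = 0.454 with an estimated correlation), and 0.61, -0.1 and 0.72 by batch; none rose adjusted over the list alone. Calcium handling genes had 0.29 with 21 of 29 above 0, and 2 rose adjusted over the list alone (adjusted p 1.15e-05, adjusted p = 0.454 with an estimated correlation; 0.51, -0.11 and 0.47 by batch). ASPH, of the calcium release complex, had 1.13 (SE 0.2, adjusted p 0.165), SRL, a calcium-binding protein of the sarcoplasmic reticulum, 1.4 (SE 0.3) and PLN, which restrains the calcium pump, 1.41 (SE 0.44). In batch B, where sarcomere genes were highest in every genotype, the differences in these 4 lists were the smallest. The ventricular median was 0.42 without RQ replicate 3, and that of RBM20 splicing targets 0.25 without RQ replicate 3 or wild-type replicate 1.

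Energy and mitochondrial lists had small medians in RQ. Fatty acid oxidation genes had a median of 0.12 (25 of 31 above 0; adjusted p 0.00315, adjusted p = 0.708 with an estimated correlation) and complex I genes 0.14 (27 of 37; 0.0421, adjusted p = 0.708 with an estimated correlation). The fatty acid transporter SLC27A6 had 1.58 (SE 0.39). The mitochondrial mRNAs had -0.33 with none of 13 above 0 (adjusted p 0.00106, adjusted p = 0.708 with an estimated correlation) and -0.25, -0.19 and -0.42 by batch. Integrated and mitochondrial stress response genes were at -0.29 with 2 of 28 above 0, an adjusted p of 5.34e-06 and an adjusted p = 0.454 with an estimated correlation; their batch means were -0.4, -0.13 and -0.34. The serine pathway gene SHMT2 had -0.41 (SE 0.18) and ATF4 -0.28. Cytosolic ribosome genes had -0.19, with 1 of 72 above 0 (adjusted p 3.93e-10, adjusted p = 0.587 with an estimated correlation), and -0.25, 0.06 and -0.39 by batch. Stress granule and P-body genes had -0.05 with 6 of 40 above 0 (adjusted p 0.0424, adjusted p = 0.723 with an estimated correlation). None of these lists had a member past the threshold over all genes or adjusted over the list alone. Camera no longer called, with 1 library left out, fatty acid oxidation genes without RQ replicate 3 (0.08, 0.149) or wild-type replicate 1 (0.03, 0.681); complex I genes without RQ replicate 1 (0.12, 0.0504), RQ replicate 2 (0.12, 0.101), RQ replicate 3 (0.14, 0.248), wild-type replicate 1 (0.08, 0.434) or wild-type replicate 2 (0.04, 0.142); mitochondrial mRNAs without wild-type replicate 1 (-0.22, 0.114); stress granule and P-body genes without RQ replicate 1 (-0.02, 0.618), wild-type replicate 1 (-0.02, 0.613) or wild-type replicate 3 (-0.07, 0.432). The ribosome median was -0.12 without wild-type replicate 1 and -0.33 without wild-type replicate 3.

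Other cell types and responses differed as follows between RQ and wild type. Endothelial markers had -0.46 with 1 of 17 above 0 (adjusted p 0.00222, adjusted p = 0.723 with an estimated correlation; -1.25, 0.85 and -0.49 by batch), and VWF, the clotting factor of endothelium, had -1.44 (SE 0.51). Epicardial markers had -0.89 with 2 of 13 above 0 (0.00548, adjusted p = 0.708 with an estimated correlation; -0.51, 0.38 and -1.68). Fibroblast markers had 0.31 with 13 of 14 above 0 (0.0306, adjusted p = 0.723 with an estimated correlation; 0.12, 1.71 and -0.16), and a median of -0.22 without wild-type replicate 3, where camera called them lower. Targets of p53 had -0.19 with 3 of 20 above 0 (0.00106, adjusted p = 0.454 with an estimated correlation) and CDKN1A, which arrests the cell cycle, -0.56 (SE 0.29). Hypoxia response genes had -0.19 (3 of 20; 0.005, adjusted p = 0.708 with an estimated correlation) and endoplasmic reticulum stress genes 0.17 (15 of 17; 0.0163, adjusted p = 0.479 with an estimated correlation). Camera called 16 of 42 lists, 8 higher and 8 lower, and 0 with an estimated correlation. Leaving out 1 library ended the camera call of endothelial markers without wild-type replicate 2 (0.23, 0.249); epicardial markers without RQ replicate 2 (-0.45, 0.193), RQ replicate 3 (-0.64, 0.0629) or wild-type replicate 1 (-0.12, 0.87); fibroblast markers without RQ replicate 1 (0.35, 0.0504), RQ replicate 2 (0.29, 0.078) or RQ replicate 3 (0.16, 0.248); p53 targets without wild-type replicate 1 (-0.13, 0.114); hypoxia response genes without RQ replicate 3 (-0.03, 0.296) or wild-type replicate 3 (-0.1, 0.696); endoplasmic reticulum stress genes without RQ replicate 1 (0.14, 0.16), RQ replicate 3 (0.18, 0.0629), wild-type replicate 2 (0.19, 0.0696) or wild-type replicate 3 (0.1, 0.151).

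**Figure D3:**
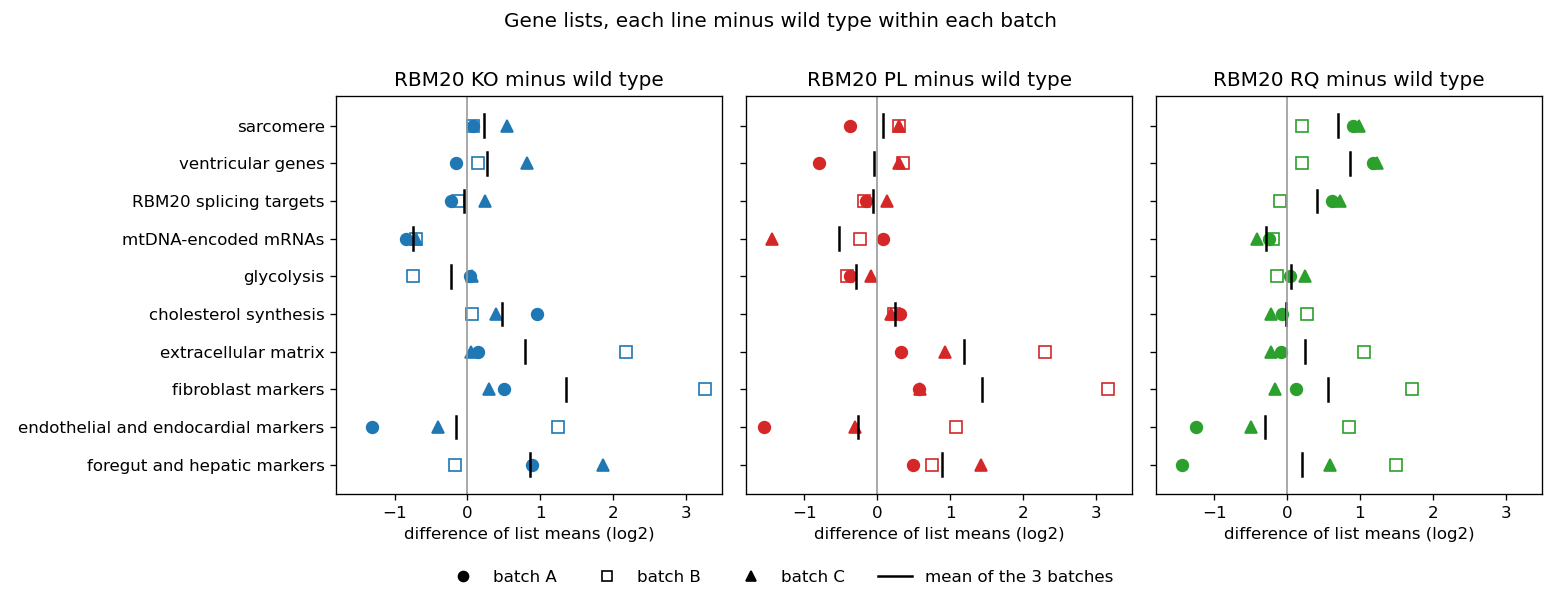
Mean log2 difference of gene lists between each altered line and wild type, with a point for each batch and the mean of the 3 batches. Mitochondrial mRNAs in KO lie at -0.84, -0.7 and -0.71 by batch, while the sarcomere list in RQ lies at 0.9, 0.21 and 0.99 and fibroblast markers in KO at 0.5, 3.26 and 0.29.

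The 3 comparisons share the wild-type libraries, which alone makes their fold changes resemble each other. Across 21844 genes, which are not independent replicates, Pearson's r was 0.56 for KO with PL, 0.31 for KO with RQ and 0.39 for PL with RQ, beside 0.49 (SD 0.01, 10 simulations) for simulated unchanged groups that share 3 controls. With DESeq2 fold changes (no simulation) r was 0.15, 0.28 and 0.2. The covariances were 0.32, 0.17 and 0.19 beside a simulated 0.19 (SD 0.007), differences of 0.13, -0.02 and 0. Signs matched in 74.1, 57.2 and 57.9% of genes, beside 66.6%. Cell content was not simulated, so the cause of these gaps is open. GC was the only gene called by edgeR in both PL and RQ; in KO edgeR called none. The DESeq2 counts for KO were above, and those for PL and RQ within, the range of 3 other splits that exchange libraries within batches, which gave 683 to 858 genes for KO (real 914), 613 to 1122 for PL (real 892) and 606 to 804 for RQ (real 744). NKAIN3, a membrane protein that binds the sodium pump and was chosen after its values were seen, had 18.3 CPM (SD 0.868) in wild type, 1.32 (SD 0.91) in KO, 1.91 (SD 2.47) in PL and 1.48 (SD 0.854) in RQ. Its fold changes were -4.19, -3.96 and -4 in KO, PL and RQ, at adjusted p values of 0.129, 0.182 and 0.102.

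Between PL and KO, neural and matrix genes were higher in PL. Neural and neural crest markers had a median of 0.85 with 10 of 11 above 0, and 0.73, 0.65 and 0.56 by batch; 1 rose adjusted over the list alone. The growth cone protein GAP43 had 0.91 (SE 0.33). The list had a camera adjusted p of 0.000509 and an adjusted p = 0.207 with an estimated correlation. Extracellular matrix genes had 0.36 with 31 of 38 above 0 and 0.18, 0.13 and 0.88 by batch (7.22e-06, adjusted p = 0.982 with an estimated correlation), TGF-beta response genes 0.26 with 15 of 20 (0.00244, adjusted p = 0.982 with an estimated correlation) and smooth muscle markers 0.36 with 9 of 13 (0.0405, adjusted p = 0.982 with an estimated correlation). Cholesterol synthesis genes had -0.22 with none of 24 above 0 (0.000466), sarcomere genes -0.18 with 9 of 34 above 0 (0.0247) and heat shock genes -0.08 (0.0247), each with an adjusted p = 0.982 with an estimated correlation. Camera called 7 of 42 lists; the count was 3 without KO replicate 2 and 18 without KO replicate 3. By edgeR 0 genes passed, with 535 at an unadjusted p below 0.05 and 809 called by DESeq2. The leading gene PCDHGC3, a protocadherin chosen after its values were seen, had 1.34 (SE 0.21) at an adjusted p of 0.407, and INPP5F had 1.21 (SE 0.22) at the same value. The camera call ended for neural markers without KO replicate 1 (0.45, 0.179), KO replicate 2 (0.54, 0.0635) or PL replicate 2 (0.34, 0.0517); extracellular matrix genes without KO replicate 2 (0.12, 0.271) or PL replicate 2 (0.11, 0.0517); TGF-beta response genes without KO replicate 2 (0.13, 0.27) or PL replicate 3 (0.23, 0.0749); smooth muscle markers without KO replicate 1 (0.2, 0.231), KO replicate 2 (0.22, 0.364), PL replicate 2 (0.53, 0.0517) or PL replicate 3 (0.18, 0.68); cholesterol synthesis genes without KO replicate 1 (0.05, 0.858); sarcomere genes without KO replicate 2 (-0.02, 0.419) or PL replicate 1 (0.02, 0.85); heat shock genes without KO replicate 1 (-0.09, 0.173), KO replicate 2 (-0.05, 0.14), PL replicate 1 (-0.05, 0.85) or PL replicate 3 (-0.02, 0.223).

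Between RQ and KO, 7 genes passed, and 6 of them are described here. ZDBF2 was higher in RQ by 6.76 (SE 0.51, adjusted p 0.000952), from 1.51 CPM (SD 1.15) in KO, and ZNF208 by 1.42 (SE 0.21, adjusted p 0.0438). LY6E, an interferon-induced surface protein, fell by 2.31 (SE 0.29, adjusted p 0.0268). TRIM4 (chromosome 7, 99876958 to 99919531, minus strand), a ubiquitin ligase, had 0, 0.839 and 0.0986 CPM in RQ and 11.6, 8.87 and 5.67 in KO, a fold change of -4.97 (SE 0.69, adjusted p 0.0456). MTLN (chromosome 2, 110211529 to 110245420, minus strand), which encodes a micropeptide of the inner mitochondrial membrane, had 3 counts in the RQ libraries and 206 in the KO libraries, a ratio of 80.3 (95% counting interval 27.1 to 393) for KO over RQ after scaling to library size. AC003973.3, an unnamed gene outside the naming rule and chosen after its values were seen, had 2.21 (SE 0.32, adjusted p 0.0438). At an unadjusted p below 0.05 there were 2117 genes, and DESeq2 called 1044. The edgeR count was 179 without RQ replicate 1, 20 without KO replicate 3, and 1 without KO replicate 1, KO replicate 2 or RQ replicate 3.

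Contractile genes were higher and ribosome, sterol and matrix genes lower in RQ than in KO. Sarcomere genes had a median of 0.6 with 29 of 34 above 0; adjusted over the list alone 3 rose and 1 fell, over all genes 0 (camera adjusted p 7.02e-07; adjusted p = 0.663 with an estimated correlation; 0.82, 0.13 and 0.45 by batch). RBM20 splicing targets had 0.47 with 20 of 24 above 0, of which 11 rose and 1 fell adjusted over the list alone (1.97e-06, adjusted p = 0.663 with an estimated correlation; 0.83, 0.02 and 0.49). TRDN, an anchor of the calcium release complex, had 1.36 (SE 0.33), RYR2 0.94 (SE 0.26), TTN 1.02 (SE 0.33) and the kinase gene CAMK2G -0.92 (SE 0.19). Ventricular genes had 0.53 with 2 risen adjusted over the list alone (0.00126, adjusted p = 0.663 with an estimated correlation), ion channel genes 0.33 with 19 of 21 above 0 and 1 risen (0.00684, adjusted p = 0.663 with an estimated correlation), and calcium handling genes 0.21 with 6 risen (0.00786, adjusted p = 0.663 with an estimated correlation). KCNJ2, the inward rectifier potassium channel, had 1.05 (SE 0.25). The mitochondrial mRNAs had 0.4 with 13 of 13 above 0 and 0.59, 0.51 and 0.29 by batch (0.00786, adjusted p = 0.71 with an estimated correlation), and glycolysis genes had 0.18 with 2 risen adjusted over the list alone (0.00692, adjusted p = 0.71 with an estimated correlation). Without KO replicate 3 the glycolysis median was 0.02 and camera called 8 lists instead of 15. Calls that ended with 1 library left out were those of ventricular genes without RQ replicate 3 (0.32, 0.237); ion channel genes without KO replicate 1 (0.24, 0.0632) or KO replicate 3 (0.27, 0.11); calcium handling genes without KO replicate 3 (0.16, 0.111), RQ replicate 2 (0.19, 0.0844) or RQ replicate 3 (0.13, 0.0986); mitochondrial mRNAs without KO replicate 1 (0.19, 0.149), KO replicate 3 (0.29, 0.111), RQ replicate 1 (0.29, 0.0603) or RQ replicate 2 (0.27, 0.0929); glycolysis genes without KO replicate 3 (0.02, 0.912).

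Cytosolic ribosome genes had -0.33 in this comparison with 2 of 72 above 0 (1.03e-15, adjusted p = 0.663 with an estimated correlation; -0.39, -0.19 and -0.43 by batch), and the protein RPL35 of the large subunit had -0.57 (SE 0.17). Cholesterol synthesis genes had -0.61 with 1 of 24 above 0, and 4 fell adjusted over the list alone (3.28e-09, adjusted p = 0.663 with an estimated correlation; -1.03, 0.2 and -0.61). SQLE, a rate-limiting sterol enzyme, had -0.77 (SE 0.21) and the sterol sensor partner INSIG1 -1.11 (SE 0.32). Matrix genes had -0.7 with 5 of 38 above 0 (7.02e-07) and fibroblast markers -0.94 with none of 14 (1.5e-05; -0.39, -1.55 and -0.45 by batch), each with an adjusted p = 0.663 with an estimated correlation. Stress response genes of the integrated pathway had -0.3 (7.92e-06), epicardial markers -0.58 (0.0102) and p53 targets -0.13 (0.0342), each with an adjusted p = 0.663 with an estimated correlation. Immediate early genes had -0.37 with 1 risen and 2 fallen adjusted over the list alone (0.00126, adjusted p = 0.67 with an estimated correlation); FOSL2 and KLF4, transcription factors of that group, had -1.07 (SE 0.22) and -1.8 (SE 0.43). Camera called 7 lists higher and 8 lower, and 0 with an estimated correlation. Camera no longer called, with 1 library left out, extracellular matrix genes without KO replicate 3 (-0.19, 0.11); fibroblast markers without KO replicate 3 (-0.5, 0.111); epicardial markers without KO replicate 1 (-0.3, 0.216) or RQ replicate 2 (-0.51, 0.0898); p53 targets without KO replicate 1 (-0.13, 0.192), KO replicate 3 (-0.16, 0.111) or RQ replicate 1 (-0.09, 0.205); immediate early genes without KO replicate 3 (-0.25, 0.111). Without KO replicate 1 the cholesterol median was -0.27, and without KO replicate 2 that of integrated stress response genes was -0.53.

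Between RQ and PL, 12 genes passed, the most of any comparison, and 11 of them are described here. ZDBF2 was higher in RQ by 6.34 (SE 0.49, adjusted p 0.00135), and ADRB3, the beta-3 adrenergic receptor, by 1.92 (SE 0.3, adjusted p 0.0425). FAM153CP, a non-coding RNA gene, had 224 counts in the RQ libraries and 2 in the PL libraries, a ratio of 100 (95% counting interval 27.4 to 833) after scaling. TRIM4 was 30.5, 17.2 and 34.3 CPM in PL and at most 0.839 in RQ, a fold change of -6.59 (SE 0.71, adjusted p 0.0093). Lower in RQ were also NNMT, which methylates nicotinamide, by -4.93 (SE 0.66, adjusted p 0.0254), the smooth muscle actin ACTG2 by -4.71 (SE 0.61, adjusted p 0.04), the secreted proteins SSC5D and THBS2 by -2.98 (SE 0.42, adjusted p 0.0325) and -2.11 (SE 0.32, adjusted p 0.0401), VAT1L by -2.07 (SE 0.31, adjusted p 0.04) and LY6E by -1.89 (SE 0.28, adjusted p 0.0403). MTLN had 3 counts in RQ and 171 in PL, a ratio of 63.7 (95% counting interval 21.4 to 312) for PL over RQ. At an unadjusted p below 0.05 there were 2001 genes, and DESeq2 called 1182. The edgeR count was 258 without RQ replicate 1 and 1 to 28 without another library.

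**Figure D4:**
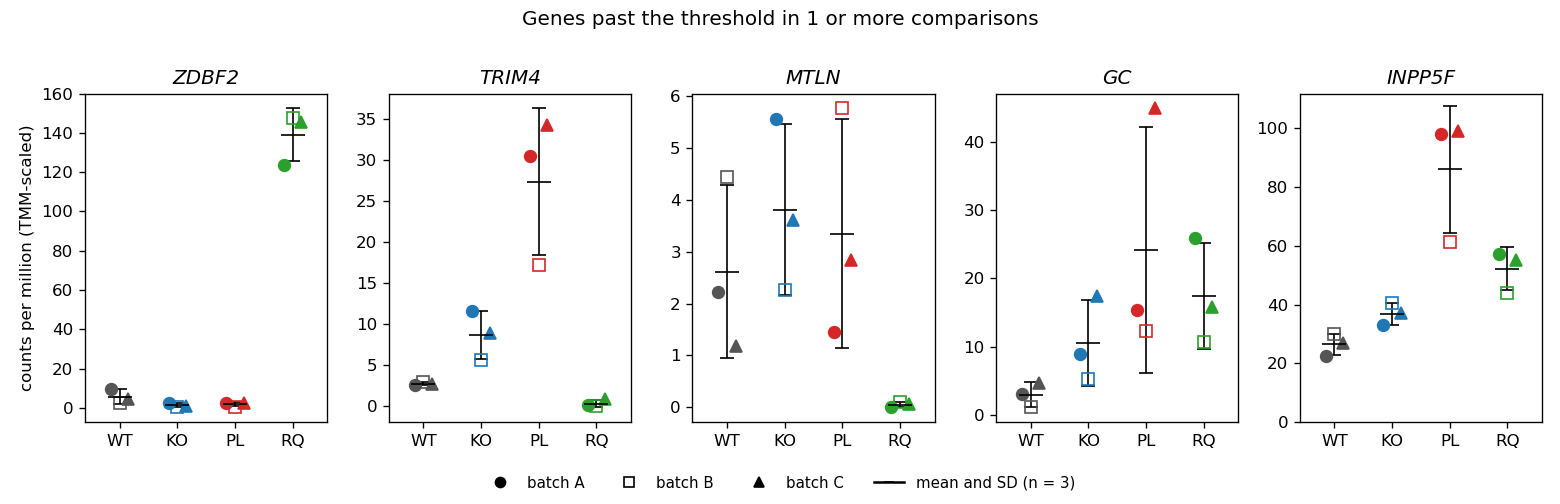
CPM per library of ZDBF2, TRIM4, MTLN, GC and INPP5F, each past the threshold in at least 1 comparison, by genotype, with the mean and SD (n = 3) and the batch as marker. ZDBF2 lies near 139 CPM in RQ and below 10 in the other 9 libraries, and TRIM4 lies between 17.2 and 34.3 in PL and at most at 0.839 in RQ.

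Contractile genes were higher and matrix genes lower in RQ than in PL. Matrix genes had a median of -1.08 with 3 of 38 above 0; adjusted over the list alone 15 fell and 1 rose, over all genes tested 0 of this list (camera adjusted p 1.17e-18; adjusted p = 0.403 with an estimated correlation; -0.41, -1.24 and -1.15 by batch). TIMP1 had -2.07 (SE 0.35, adjusted p 0.0915) and fibronectin, FN1, -1.43 (SE 0.33). Fibroblast markers had -1.04 with 1 of 14 above 0 (6.52e-06, adjusted p = 0.461 with an estimated correlation) and TGF-beta response genes -0.44 with 2 fallen adjusted over the list alone (1.61e-05, adjusted p = 0.403 with an estimated correlation). Sarcomere genes had 0.87 with 29 of 34 above 0; adjusted over the list alone 16 rose and 2 fell (1.07e-12, adjusted p = 0.403 with an estimated correlation; 1.27, -0.09 and 0.69 by batch). RBM20 splicing targets had 0.54 with 20 of 24 above 0, of which 14 rose and 2 fell adjusted over the list alone (4.52e-09, adjusted p = 0.403 with an estimated correlation; 0.76, 0.08 and 0.58). The M-line gene MYOM1 had 1.28 (SE 0.27), TNNT2, cardiac troponin T, 1.19 (SE 0.27), RYR2 1.12 (SE 0.26), TTN 1.17 (SE 0.33), and the splicing regulator RBM24 1.33 (SE 0.27, adjusted p 0.105). In batch B, with the highest sarcomere levels, the sarcomere mean difference was below 0.

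Calcium handling genes had 0.16 with 8 risen and 1 fallen adjusted over the list alone (0.00155), ion channel genes 0.28 with 5 risen (0.00199), heat shock genes 0.19 with 1 risen (0.00266) and ventricular genes 0.95 with 1 risen (4.61e-07), each with an adjusted p = 0.403 with an estimated correlation. Ventricular batch means were 1.98, -0.14 and 0.93. Glycolysis genes had 0.24 with 23 of 25 above 0, 4 risen adjusted over the list alone, and 0.42, 0.28 and 0.33 by batch (3.01e-05, adjusted p = 0.461 with an estimated correlation). Splicing regulators had 0.16 with 1 risen (0.00301, adjusted p = 0.473 with an estimated correlation) and fatty acid oxidation genes 0.13 with 1 risen (0.0247, adjusted p = 0.58 with an estimated correlation). Ribosome genes had -0.31 with 4 of 72 above 0 (5.77e-11), stress response genes of the integrated pathway -0.33 (0.000162), interferon response genes -0.56 with 5 of 23 above 0 (0.00886) and endoplasmic reticulum stress genes -0.15 (0.0191), each with an adjusted p = 0.403 with an estimated correlation. Interferon genes were at -0.39, -0.34 and -0.61 by batch, and IFIT2, an antiviral effector, had -1.21 (SE 0.39). Cholesterol synthesis genes had -0.36 (0.00192), immediate early genes -0.43 with 1 fallen adjusted over the list alone (0.00345) and epicardial markers -0.34 (0.0191), each with an adjusted p = 0.517 with an estimated correlation. Targets of p53 had -0.27 (0.00886, adjusted p = 0.461 with an estimated correlation) and foregut and hepatic markers -0.26 (0.0191, adjusted p = 0.527 with an estimated correlation; -1.94, 0.74 and -0.84 by batch). Camera called 21 of 42 lists, 9 higher and 12 lower, and 0 with an estimated correlation. Leaving out 1 library ended the camera call of heat shock genes without PL replicate 1 (0.26, 0.226); splicing regulators without PL replicate 3 (0.13, 0.0681); fatty acid oxidation genes without PL replicate 1 (0.06, 0.347) or RQ replicate 3 (0.08, 0.208); interferon response genes without RQ replicate 2 (-0.5, 0.0643); endoplasmic reticulum stress genes without RQ replicate 2 (-0.12, 0.0618); cholesterol synthesis genes without RQ replicate 3 (-0.18, 0.0558); immediate early genes without PL replicate 3 (-0.25, 0.0697) or RQ replicate 3 (-0.36, 0.12); epicardial markers without PL replicate 1 (-0.31, 0.0651), PL replicate 2 (0.01, 0.525), RQ replicate 2 (-0.12, 0.193) or RQ replicate 3 (-0.27, 0.108); p53 targets without PL replicate 2 (-0.19, 0.155) or RQ replicate 1 (-0.1, 0.102); foregut and hepatic markers without PL replicate 1 (-0.34, 0.0615) or RQ replicate 3 (-0.16, 0.719). Some medians moved over the 14 alternatives. Foregut and hepatic ran from -2.21 to -0.16, ventricular genes from 0.31 to 1.43 and sarcomere genes from 0.46 to 1.32. Endoplasmic reticulum stress ran from -0.37 to -0.12, integrated stress response from -0.43 to -0.12 and ribosome genes from -0.38 to -0.19. Calcium handling ran from 0.12 to 0.27 and ion channels from 0.22 to 0.53.

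The mean of PL and RQ was also set against KO. No gene passed by edgeR, with 1016 at an unadjusted p below 0.05, a smallest adjusted p of 0.121, and 712 called by DESeq2; 3 passed without KO replicate 3 and 3 without RQ replicate 1. The leading genes, chosen after their values were seen, were ZDBF2 at 3.59 and ZNF208 at 1.28 (SE 0.19), both with an adjusted p of 0.121. ZNF208 had 21.3 CPM (SD 3.87) in PL, 25.8 (SD 2.31) in RQ and 9.65 in KO.

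The authors' deposited table for KO against wild type lists 340 genes at an adjusted p below 0.05, 280 higher and 60 lower. The authors' deposited table for PL lists 112 genes, 82 higher and 30 lower, and the authors' deposited table for RQ lists 570, 357 higher and 213 lower. Recomputing DESeq2 from the counts of the libraries of batches A and C alone, 2 per group, gave 340 genes for KO, 116 for PL and 570 for RQ. Of these, 340, 112 and 570 are in the authors' deposited tables, which therefore rest on those 2 batches. In the authors' deposited table for RQ, MYL2 has 3.18, the neuroendocrine gene CHGA 3.67, MYH7 2.2 and TTN 1.35, and 23 of 32 sarcomere genes and 12 of 24 RBM20 splicing targets are higher. In the authors' deposited table for KO, COX7A1 is lower, 3 of 13 mitochondrial mRNAs are lower (MT-ND1, MT-ND2 and MT-ND5), and 7 of 18 foregut and hepatic markers are higher. In the authors' deposited table for PL, the highest values include NNMT at 4.05 and TRIM4 at 3.61. Across the authors' deposited tables, 11 genes are past the threshold in the same direction in all 3, 5 higher (AMBP, CHGA, GC, ITIH2, MYL2) and 6 lower, among them NKAIN3 at -3.34, -3.23 and -3.25 and the natriuretic peptide clearance receptor NPR3 at -1.79, -1.72 and -1.56.

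The 12-library fit holds batches A and C too, which favours equal signs. Of tested genes called in the authors' deposited tables, 337 of 337 (KO), 112 of 112 (PL) and 569 of 570 (RQ) kept their sign. In batch B, outside those tables, 177 of 337, 75 of 112 and 237 of 570 did, near even for KO and a minority for RQ. Of edgeR calls, 0, 2 and 4 are in the authors' deposited tables for KO, PL and RQ. With batches A and C alone, chosen after seeing the data, edgeR called 23, 17 and 62 genes.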

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

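The tests of cell dilution, endodermal cells, batch B and cell content were chosen after the results were seen. So were the imprinted list, which leaves out genes already seen, and 2 added conditions of its test (gene p and range between batches). The counts over other splits were set before. The genes in this part stand out because their effects against wild type differ between altered lines, by the edgeR contrast of the lines themselves (3 libraries per line, all 12 in the fit).

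Between RQ and KO the difference of effects was 6.76 for ZDBF2, 1.42 for ZNF208, 2.21 for the unnamed gene AC003973.3, -2.31 for LY6E, -4.97 for TRIM4 and -6.3 for MTLN, on the log2 scale. Between RQ and PL it was 6.34 for ZDBF2, 6.64 for the non-coding gene FAM153CP, 1.92 for ADRB3, -6.59 for TRIM4, -5.86 for MTLN, -4.93 for NNMT, -4.71 for ACTG2, -2.98 for SSC5D, -2.11 for THBS2, -2.07 for VAT1L and -1.89 for LY6E. Fitted values of MTLN and FAM153CP depend on the prior count, since MTLN had 3 counts over the RQ libraries and FAM153CP 2 over the PL libraries. In the 14 alternatives run for each, ZDBF2 stayed between 6.15 and 7.3 against KO and between 5.76 and 6.82 against PL, and TRIM4 between -8.9 and -6.07 against PL.

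Among the genes that differ between RQ and PL, the first pattern, ZDBF2 and TRIM4 stayed past the threshold when a score of cell content per library, sarcomere minus fibroblast genes, was added to the fit (largest adjusted p 0.0106), which argues against cell content as their whole cause. For 9 other genes the score left a median absolute fold change of 2.4, from 2.98 without it, while the median SE went from 0.42 to 0.53 and 0 of the 9 stayed past the threshold. Cell content therefore cannot be told apart from line for these 9, because the estimate shrank little and its error grew. Imprinted genes other than those already seen had a median absolute difference of 0.53 beside 0.23 in random lists matched on expression, at percentile 100, and at 98.7 by gene p, yet they were also at percentile 100 for the range between batch means and 0 of 41 was called. In other comparisons the percentile was 67.4 for PL against KO, 98.3 for RQ against KO and 96.2 for KO against wild type. The PL against KO value goes against genes that vary in any culture and the batch range goes with them, so a difference in imprinting cannot be told apart from such genes. The alteration of RBM20 and the history of each line, both untested with 1 line per genotype, may account for ZDBF2 and TRIM4 (0.0106 above).

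The second pattern is the higher sarcomere level of RQ against wild type. A larger cardiomyocyte share that thins every other cell type alike cannot be told apart from other causes. Fibroblast markers exceeded endothelial markers in the RQ minus wild-type difference by 0.85 on average (SD 0.52; 1.37, 0.86 and 0.33 by batch), but without wild-type replicate 2 the gap between the list medians was 0.3. With each of the other libraries of RQ and wild type left out it was 0.6 to 1.14, and without wild-type replicate 3 (0.84) both medians lay below 0, at -0.22 and -1.06. A change in the number or maturity of cardiomyocytes alone, with other cell types moving on their own, stays open, as does the genotype. The difference was small in batch B (0.21) and may depend on how rich the wild-type cultures of batches A and C were in cardiomyocytes.

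The third pattern is the higher foregut and hepatic level of KO and PL. A candidate is endodermal cells in some cultures. A separate list of 24 gut epithelium genes, written after the data were seen, followed the foregut and hepatic list over the 8 libraries of batches A and C. Spearman's rho was 0.88 and Pearson's r 0.93 (0.89 without the 2 libraries farthest from the median). In both batches both lists ordered the 4 libraries alike (mean rho 1, mean r 0.99). Exact p over 576 permutations within batches was 0.00347 (rho) and 0.00174 (r), descriptive only for a list so written. APOA4, an abundant gene of small intestine, had 943 CPM in KO, 461 in PL, 7.74 in RQ and 387 in wild type in batch A, 611, 476, 251 and 144 in batch C, and 0 to 4.49 in batch B. If genotype drove both lists they would match too, so this cannot tell it from cells. Batch B cannot either, with list means near the floor, 1.68 log2 CPM against 5.47 elsewhere. There the difference from wild type was -0.17 for KO (0.89 in batch A and 1.86 in batch C) and 0.75 for PL (0.49 and 1.43). The labels name no sort or gate that would remove endodermal cells.

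Other splits of the 6 libraries of each pair of genotypes number 10 with the real one, too few for a share under 0.05. For KO against wild type 10 of 10 splits gave at least the real 0 genes (highest other 0) and 7 at least the real 10 lists (highest other 22). For PL against wild type 1 gave the real 2 genes (highest other 0) and 7 the real 15 lists (highest other 26), and for RQ against wild type 1 gave 4 genes (0) and 5 gave 16 lists (22). For PL against KO 10 gave 0 genes (0) and 10 gave 7 lists (19), for RQ against KO 1 gave 7 genes (5) and 4 gave 15 lists (24), and for RQ against PL 1 gave 12 genes (0) and 1 gave 21 lists (16). The split of RQ and KO with 5 genes set KO replicates 1 and 2 with RQ replicate 1 against the rest and exchanged libraries within batch B. Splits that exchange libraries within a batch, keeping the batches balanced, gave up to 22, 16, 22, 19, 12 and 15 lists in the 6 comparisons in the order above. With DESeq2, the 3 other splits within batches gave 683 to 858 genes for KO against wild type (real 914), 613 to 1122 for PL (real 892) and 606 to 804 for RQ (real 744). For the mean of PL and RQ against KO, 40 of 40 drawn splits gave at least the real 0 genes, as any split must, so this says nothing about chance. The 3 splits with the most genes, 152, 129 and 93, all set KO replicate 2 with RQ replicates 2 and 3 against the rest, which points to a structure of the samples whose source was not tested.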

How the results depend on the processing

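The alternative with batches A and C only and the cell-content covariate were chosen after seeing the data, and all other alternatives were planned. With RLE size factors, and without genes of mitochondrial DNA and ribosomal RNA, every comparison kept its count of genes and lists within 1.5 times; RLE gave 11 genes for RQ against PL in place of 12. No named gene past the threshold changed sign under any alternative. Several that were not past it did, most of them with fold changes near 0, and MYH7 in PL against KO went from -0.48 to 0.2 with the replicate number as block. The genes called by edgeR are all among those called by DESeq2, with no filter, with batches A and C only and, in the comparisons that include RQ, without RQ replicate 1, so these settings add calls. Where a value moved, the cause was not tested, except that fewer libraries leave fewer residual degrees of freedom (2 with 6 libraries, 3 with the 8 libraries of batches A and C). In the self-test on RQ against wild type DESeq2 made 182 calls of which 50 were unchanged genes, and edgeR 119 with 6. At this number of libraries edgeR recovered 4% of genes changed 1.5-fold and 32% of those changed 2-fold, so smaller changes were mostly not detectable.

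Counts of genes changed with no filter on low counts (42967 genes tested) were 502 for KO, 563 for PL and 297 for RQ against wild type, 62 for PL against KO, 891 for RQ against KO, 944 for RQ against PL and 226 for the mean of PL and RQ against KO. With DESeq2 they were 914, 892, 744, 809, 1044, 1182 and 712 in the same order. With batches A and C only they were 23, 17, 62, 12, 449, 387 and 80. With no batch term, and with the replicate number as replicate block in place of batch, the counts for PL and RQ against wild type, RQ against KO and RQ against PL were all 0. With only the 6 libraries compared they were 8 for PL and 0 for RQ against wild type, 1 for PL against KO, 0 for RQ against KO and 98 for RQ against PL.

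Leaving out 1 library at a time gave 0 to 2 genes for KO against wild type, 0 to 4 for PL against wild type, 0 to 37 for RQ against wild type, 1 to 179 for RQ against KO, 1 to 258 for RQ against PL and 0 to 3 for the mean of PL and RQ against KO. The highest values came without wild-type replicate 3 (2), PL replicate 1 (4), RQ replicate 1 (37, 179 and 258) and either KO replicate 3 or RQ replicate 1 (3). Counts under the reported ones came without PL replicate 3 or wild-type replicate 1 or 2 (0) and PL replicate 2 (1) for PL against wild type, and without wild-type replicate 1 (0) and RQ replicate 3 (1) for RQ against wild type. For RQ against KO they came without KO replicate 1, KO replicate 2 or RQ replicate 3 (1) and RQ replicate 2 (6), and for RQ against PL without RQ replicate 2 (4) and PL replicate 2, PL replicate 3 or RQ replicate 3 (1). Without wild-type replicate 3 RQ against wild type gave 9, without KO replicate 3 RQ against KO gave 20, and without PL replicate 1 RQ against PL gave 28. RBM20 in RQ against wild type was 0.9 with no filter (adjusted p 0.00404) and 0.54 to 1.22 with a library left out, past the threshold only without RQ replicate 1 (1.22); its adjusted p was 0.746 in the fit reported.

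Counts of lists changed were 0 in all 6 comparisons with camera at an estimated correlation and 0 with fry for movement one way. With fry for change in either direction they were 1 for KO, 0 for PL and 0 for RQ against wild type, 1 for PL against KO, 1 for RQ against KO and 4 for RQ against PL. For PL against KO the count was 4 with no filter, 4 with the replicate number as block and 18 with batches A and C only. For RQ against wild type it was 10 with no batch term. Leaving out 1 library gave 3 (without KO replicate 2) to 18 lists (without KO replicate 3) for PL against KO and 8 (without KO replicate 3) to 17 for RQ against KO.

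With batches A and C only 20 of 84 calls ended (median then in parentheses): in KO against wild type cytosolic ribosome (0.08), extracellular matrix (0.12), glycolysis (0.02), hypoxia response (-0.05) and immediate early (0.17); in PL against wild type immediate early (0.06), neural (0.24) and stress granule and P-body (-0.09); in RQ against wild type endoplasmic reticulum stress (0.14), fibroblast (-0.02), hypoxia response (-0.18) and stress granule and P-body (-0.02); in RQ against KO ion channel (0.26), glycolysis (0.04), immediate early (-0.23), mitochondrial mRNAs (0.24) and p53 targets (-0.11); in RQ against PL endoplasmic reticulum stress (-0.14), epicardial (-0.79) and p53 targets (-0.06). With no batch term 25 ended: in KO against wild type glycolysis and immediate early; in PL against wild type cholesterol synthesis, endothelial, heat shock, immediate early and neural; in RQ against wild type calcium handling, fatty acid oxidation, fibroblast, hypoxia response, complex I and stress granule and P-body; in PL against KO heat shock and sarcomere; in RQ against KO calcium handling, ion channel, glycolysis, RBM20 splicing targets, sarcomere and ventricular; in RQ against PL calcium handling, ion channel, fatty acid oxidation and heat shock. With the replicate number as block 21 ended: smooth muscle in PL against KO and the lists just named, except hypoxia in RQ against wild type, splicing targets, sarcomere and ventricular in RQ against KO and heat shock in RQ against PL. With no filter 10 ended: in PL against wild type endothelial and neural; in RQ against wild type fibroblast and complex I; in PL against KO heat shock, sarcomere and smooth muscle; in RQ against KO calcium handling; in RQ against PL calcium handling and fatty acid oxidation. With only the 6 libraries compared 4 ended: in PL against wild type endothelial, immediate early and stress granule and P-body; in RQ against wild type stress granule and P-body.

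A few list medians turned. With batches A and C only, fibroblast markers in RQ against wild type were at -0.02 and glycolysis genes in KO against wild type at 0.02. With a library left out, cholesterol genes in PL against KO ran from -0.48 to 0.05 (without KO replicate 1), and endothelial markers from -1.04 to 0.24 in PL and from -1.06 to 0.23 in RQ against wild type (both without wild-type replicate 2). Fibroblast markers in RQ against wild type ran from -0.22 (without wild-type replicate 3) to 0.69. Glycolysis genes ran from -0.32 to -0.03 in KO against wild type, where camera's direction turned without KO replicate 3 (-0.03), and from 0.02 (without KO replicate 3) to 0.32 in RQ against KO, and sarcomere genes in PL against KO from -0.44 to 0.02 (without PL replicate 1). The sarcomere median in PL against KO was also 0.01 with no batch term and 0.17 with the replicate number as block, and that of epicardial markers in RQ against PL was 0.01 without PL replicate 2. The medians of mitochondrial mRNAs in KO against wild type stayed between -1.02 and -0.61, of sarcomere genes in RQ against wild type between 0.4 and 0.93, and of matrix genes in PL against wild type between 0.65 and 1.52.

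Pearson's r between KO and PL fold changes was 0.48 with no filter and 0.15 with DESeq2, and between PL and RQ it was 0.2 with DESeq2. At an adjusted p below 0.01 the genes shared with the authors' deposited tables were 0 for PL and 1 for RQ.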

Other observations

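Among genes not yet described, all chosen after their values were seen, several differed between genotypes. TFCP2, a transcription factor, had 19.1 CPM (SD 2.69) in PL and 41.0 (SD 2.42) in wild type, 42.5 (SD 10.2) in KO and 41.3 (SD 3.82) in RQ; against wild type the fold change in PL was -1.09 (SE 0.21, adjusted p 0.23) with -0.92, -1.4 and -0.99 by batch. EMC4, a subunit of the membrane protein insertion complex of the endoplasmic reticulum, had 19.2 CPM (SD 1.25) in PL, 38.3 (SD 5.68) in wild type, 39.9 (SD 5.05) in KO and 41.1 (SD 9.32) in RQ, with -1.05 (SE 0.19, adjusted p 0.407) against KO. DNAH11, an axonemal dynein, had 81.9 CPM (SD 44.4) in KO and 88.2 (SD 65.8) in PL, and 158 (SD 92.6) in RQ and 205 (SD 166) in wild type; its fold changes against wild type were -1.19 (SE 0.18, adjusted p 0.129) in KO and -1.21 (SE 0.18, adjusted p 0.072) in PL, with the same sign in all 3 batches in both. MAN1A1, a mannosidase of the Golgi, had 164 CPM (SD 83.4) in KO and 78.3 (SD 42.7) in wild type, a fold change of 1.1 (SE 0.18, adjusted p 0.148) with 1.3, 1.17 and 0.82 by batch. None of these passed the edgeR threshold.

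The gut epithelium list had means of 6.14 log2 CPM in KO, 5.12 in PL, 1.32 in RQ and 3.61 in wild type in batch A. In batch C they were 4.56, 4.38, 3.31 and 2.5, and in batch B -1.57, -0.28, 0.07 and -0.8.

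Fibroblast and endothelial markers in RQ against wild type had differences of 0.12 and -1.25 in batch A, 1.71 and 0.85 in batch B, and -0.16 and -0.49 in batch C. Their signs differed in batch A alone, where wild-type replicate 2 had the highest endothelial level, 6.45 log2 CPM against 4.89 to 5.2 in the other 3 libraries of that batch.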
